A study of Mus musculus with 9 samples.

How the data were processed

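Liver RNA of 9 mice was sequenced, with 3 libraries in each of 3 groups: normal diet, high-fat diet with PBS injections (HFD + PBS) and high-fat diet with injections of recombinant human IgG1 (HFD + IgG1). Per the labels, total RNA was taken from livers with Trizol and 1 µg per liver went into a NEBNext Ultra RNA library. The deposited values are whole-number counts per Ensembl gene ID, not normalised, made by the authors. The submitters' processing notes name the genome build mm10 and Bowtie 0.12.2, without saying what each was used for. The counting program, its annotation version and whether it used the strand are not given in the sources used here, so counts of overlapping genes and of near-identical genes carry an unknown share of reads of their neighbours. Precision is limited by the spread between animals and by depth, which ran from 16215194 to 18538463 counts per library.

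The table held 54532 gene IDs, of which 54409 were named from GENCODE M21 (GRCm38, the assembly also called mm10) and 123 had no name in it. Where 2 or more IDs shared a symbol, which held for 101 symbols, the Ensembl ID kept them apart. In all, 26478 IDs had at least 1 count in any library. Groups were taken from the sample titles and the series design. The diet-and-treatment label reads IgG1 for 1 of the 3 libraries of the antibody group, replicate 5, and reads IgG2 and IgG3 for the others, which the titles and the series design place in the same group.

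Counts were analysed in R 4.3.3. edgeR 4.0.16 was run with TMM factors, filterByExpr on the 3 groups (minimum count 10, minimum total count 15), a model of group means over all 9 libraries, glmQLFit with robust = TRUE and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 14763 genes that passed the filter and a threshold of 0.05. All 9 libraries shared 1 estimate of the spread. The common dispersion was 0.101, a biological coefficient of variation of 0.318. CPM values are edgeR's counts scaled to the library total times the TMM factor and are given as mean ± SD over 3 libraries. The SE of a log2 fold change was derived from edgeR's test. It is the size of the unshrunk log2 fold change over the square root of the F statistic, while the fold changes printed are edgeR's shrunken ones. A 3 against 3 exact test cannot go below a p of 0.1, so no exact test of single genes was made. Intervals and limits from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

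Gene lists were tested with camera in limma 3.58.1 on voom log2 CPM, with the same model, a correlation between genes preset at 0.01, and Benjamini-Hochberg adjustment over the 35 lists with at least 5 tested members, out of 37 (24 pathway lists and 13 lists of cell type markers). The same lists were tested with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. No list call of camera held with an estimated correlation or with fry. Members were also adjusted over the list alone. For the comparison of the diet response with the antibody response, which share the HFD + PBS libraries, the values were set beside 20 simulations with no antibody effect and beside fits in which no HFD + PBS library served both comparisons.

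The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, in each comparison, genes past the threshold with at least 1 CPM on average and no overlap between the groups' values, or else the 3 with the smallest p in each direction. It adds up to 4 members with the smallest p of each list described, and 14 genes whatever their values (Apoe, Cyp7a1, Sqle, Fasn, Scd1, Cpt1a, Cd36, Plin2, Cidec, Pparg, Fcgr2b, Trem2, Saa1 and 1 other). Values of some genes that this rule names are not reported here. Which lists to describe among those not called by camera was chosen after their values were seen, as were the Y-linked genes, Xist and the genes near Apoe.

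The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, robust = FALSE, a minimum log2 fold change of 1, only the 6 libraries compared, only the antibody library whose own label reads IgG1, no mitochondrially encoded genes, the replicate number as a block, and each library left out in turn. After the data were seen, 2 more were added: a covariate for whether a library held Y-linked reads, and a fit without the 3 libraries at odds with their labels. The workflow was tested on simulated data with the same depths and spread per gene, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Each gene was drawn independently of the others. It recovered 14, 24 and 16 of the 2-fold genes and 73, 69 and 74 of the 4-fold genes in the 3 comparisons, with 5, 5 and 3 false calls. Skeletal muscle and pancreatic acinar markers were left out of the list tests because 1 member of each passed the filter.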

Results

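RNA of 9 livers was measured as counts per gene, in 3 libraries each of normal diet, HFD + PBS and HFD + IgG1. The mice were male, of the C57BL/6 background and ApoE−/− per the labels and the series design. The high-fat diet, with 41% of calories from fat, 43% from carbohydrate and 17% from protein at 4700 kcal/kg, began at 4 weeks of age and lasted 20 weeks, followed by 1 week of chow. PBS or 3 mg of recombinant human IgG1, whose target the labels do not name, was injected into the peritoneum at 25, 26 and 27 weeks, and the mice so injected were killed at 29 weeks. The diet after 25 weeks of age is not given in the sources used here, nor are the age at death and the injections, if any, of the normal diet group. Comparisons with that group therefore cannot tell the diet from age at death or injection. Livers went to sequencing according to their Oil Red O staining and TG values, so the groups hold chosen livers. Total counts were 16873518, 18226378 and 17261599 for normal diet replicates 4, 5 and 6. They were 17941915, 18538463 and 17556558 for HFD + PBS replicates 3, 4 and 6, and 16215194, 18075415 and 18209121 for HFD + IgG1 replicates 5, 6 and 7.

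Apoe, the gene targeted in this strain (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, mm10), encodes an apolipoprotein that is among the most abundant liver mRNAs where the gene is intact. It had 235888 counts in the library labelled HFD + IgG1 replicate 5 and 225 to 1655 counts in each of the other 8. In CPM this was 16832 against 13.7 to 99.9, or 377 times the median of 44.6 CPM of the other 8. Xist, the RNA that coats the inactive X chromosome of female cells, had 17065 counts in the library labelled normal diet replicate 5 and 10970 in that labelled HFD + PBS replicate 6, and at most 4 in the other 7. Those 2 libraries had 0 counts over the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which allows up to 3, while the other 7 had 2837 to 3385. The fitted log2 fold changes of Apoe, -0.08 (SE 1.75), 7.17 (SE 2.28) and 7.10 (SE 2.27) in the 3 comparisons, the last 2 resting on 1 library, did not pass edgeR's test. These 3 libraries stay in all comparisons. Values without them are given for the called lists that lost the call or turned, or whose median moved by over 1.5 times.

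**Figure D1:**
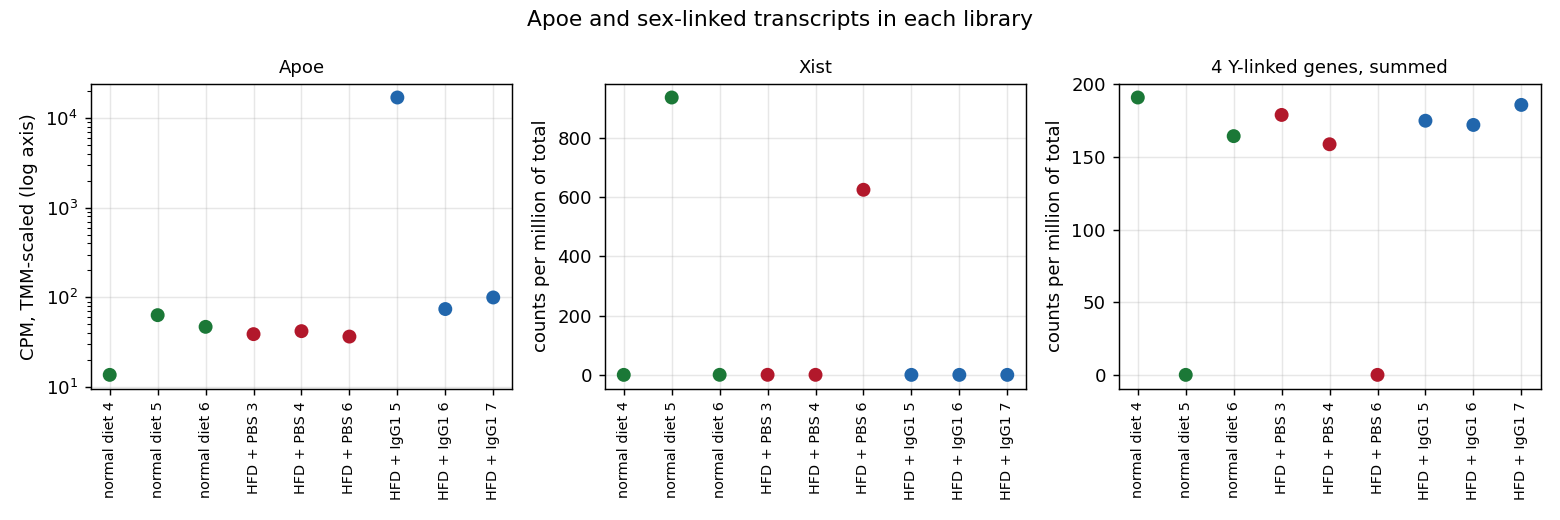
CPM of Apoe (log axis), of Xist and of 4 Y-linked genes summed, 1 point per library, by group. One HFD + IgG1 library holds 16832 CPM of Apoe against at most 99.9 in the other 8, and 2 libraries hold Xist and no Y-linked reads.

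The first comparison, HFD + PBS against normal diet, asked how the liver transcriptome of ApoE−/− mice differed after the high-fat diet. Genes of fatty acid oxidation and PPAR-alpha targets, which break fatty acids down, were lower after the high-fat diet, with a median log2 fold change of -1.25 and all 32 negative. Genes of cholesterol synthesis were higher, with a median of 1.12 and all 25 positive. Markers of neutrophils were higher by a median of 4.30 (14 of 14 positive), markers of recruited and lipid-associated macrophages by 1.56 (15 of 15) and cell cycle genes by 2.19 (30 of 30). Camera called 20 of the 35 lists, 13 higher and 7 lower, and 0 with an estimated correlation. Adjusted over each list alone, 0 genes passed in 6 of the 20: neutrophil, interferon response, acute phase, female-biased, Kupffer cell and T and NK cell.

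Single genes did not pass: edgeR called 0 of 14763 genes, with a lowest adjusted p of 0.0627, while 3076 had an unadjusted p under 0.05 (1389 higher and 1687 lower) where chance gives 738. On the same counts DESeq2 called 1138 genes (543 higher, 595 lower) and limma-voom called 0. The edgeR count was 274 with no filter on low counts, 184 with only the 6 libraries compared and 14 without HFD + PBS replicate 6. It was 576 (251 higher, 325 lower) without HFD + IgG1 replicate 6, a library outside this comparison that shares the estimate of the spread. Without the 3 libraries at odds with their labels it was 2, Retsat and Pdk4, both lower and named after their values were seen. Upper-quartile factors gave 1658 higher and 1369 lower genes at an unadjusted p under 0.05, so the balance of directions depends on the scaling.

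The smallest p values among the higher genes were those of Mvd and Fdps, which encode enzymes of the mevalonate pathway, and Myom3, which encodes a sarcomere protein. Mvd (ENSMUSG00000006517, chromosome 8, 122433601 to 122443422, mm10) had 33.0 ± 12.8 CPM in HFD + PBS and 6.12 ± 1.47 in normal diet (mean ± SD, n = 3 each), a log2 fold change of 2.43 (SE 0.32, edgeR adjusted p = 0.0627). Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959) differed by 2.68 (SE 0.43, edgeR adjusted p = 0.0627) and Myom3 by 3.40 (SE 0.56, edgeR adjusted p = 0.0644). Among the lower genes, Smad9, a transcription factor of BMP signalling (ENSMUSG00000027796, chromosome 3, 54755582 to 54801257), had 1.87 ± 0.474 CPM in HFD + PBS and 11.2 ± 3.88 in normal diet. Its log2 fold change was -2.58 (SE 0.31), that of Paqr9 was -1.54 (SE 0.20) and that of Zfpm1, a cofactor of GATA factors, was -1.50 (SE 0.20), each with an edgeR adjusted p of 0.0627.

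In the fatty acid oxidation list, 27 of 32 genes were lower when adjusted over the list alone, and 29 had no overlap between the groups, where chance gives 10% (camera adjusted p = 8.88e-21, adjusted p = 0.53 with an estimated correlation). Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein, had log2 fold changes of -1.16 (SE 0.21) and -1.04 (SE 0.20). Ppara, the nuclear receptor that drives this program, was at 36.9 ± 6.37 CPM against 116 ± 29.9 (-1.65, SE 0.32). Cpt1a, which admits fatty acids to mitochondria, was at -1.05 (SE 0.24). In the cholesterol synthesis list, 16 of 25 genes were higher when adjusted over the list alone (camera adjusted p = 7.03e-11, adjusted p = 0.53 with an estimated correlation). Pmvk was at 1.02 (SE 0.20), Lss at 1.75 (SE 0.36) and Sqle at 1.87 (SE 0.39). Without the 3 libraries at odds with their labels, both lists kept the direction of their medians, with the fatty acid oxidation median at -1.59.

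Lipid droplet and lipid uptake genes were lower on balance, with a median of -0.94 over 23 genes (camera adjusted p = 0.0112, adjusted p = 0.53 with an estimated correlation), and adjusted over the list alone 6 were lower and 3 higher. Their median was -0.49 without normal diet replicate 4. Fitm2, which helps form lipid droplets, was at -1.55 (SE 0.26), the monoglyceride lipase Mgll at -1.83 (SE 0.34), and the droplet-bound Hsd17b11 and Hsd17b13 at -1.17 (SE 0.24) and -0.94 (SE 0.21). Plin2, a coat protein of lipid droplets, had 278 ± 156 CPM against 902 ± 305 (-1.70, SE 0.41). Cidec was at -1.15 (SE 0.37), Cd36 at 0.60 (SE 0.40) and Pparg at -0.34 (SE 0.22), none past edgeR's test over all genes. Bile acid genes had a median of -0.50 over 24 (camera adjusted p = 0.0155, adjusted p = 0.53 with an estimated correlation), and the call was lost without normal diet replicate 6 (adjusted p = 0.0914, median -0.33). Cyp8b1, the 12-alpha-hydroxylase that makes cholic acid, had 13.4 ± 4.23 CPM in HFD + PBS and 487 ± 200 in normal diet (-5.18, SE 0.75), whereas Cyp2c70, which makes muricholic acids in mice, was at 1.59 (SE 0.34). Abcc3 was at -1.05 (SE 0.17), Abcb4 at -1.09 (SE 0.30), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.77 (SE 0.74). Lipoprotein genes had a median of -0.23 over 31 (camera adjusted p = 0.00854, adjusted p = 0.53 with an estimated correlation). Apoa5 was at -1.29 (SE 0.29), Lpcat3 at -0.62 (SE 0.14), Apoc2 at -2.25 (SE 0.55) and Lipc at -0.90 (SE 0.23). Without HFD + PBS replicate 3 that call was lost (adjusted p = 0.0737), and the median was -0.14 without normal diet replicate 5.

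Among the immune lists, neutrophil markers had 12 of 14 genes without overlap, all higher, where chance gives 10%, and 0 passed when adjusted over the list alone (camera adjusted p = 3.31e-08, adjusted p = 0.53 with an estimated correlation). Cxcr2, a chemokine receptor of neutrophils, was at 21.5 ± 11.9 against 3.75 ± 1.77 CPM (2.52, SE 0.91), Ly6g at 4.38 (SE 1.62), Csf3r at 1.53 (SE 0.58) and Retnlg at 3.12 (SE 1.22). Recruited macrophage markers (camera adjusted p = 8.06e-07, adjusted p = 0.53 with an estimated correlation) included Spp1, osteopontin, at 1.67 (SE 0.35), Cd9 at 1.57 (SE 0.43), Fabp5 at 1.34 (SE 0.39), Cd63 at 1.69 (SE 0.57) and Trem2, a lipid receptor of macrophages, at 1.75 (SE 0.64). Inflammatory cytokines and NF-kB targets had a median of 0.81, 25 of 26 positive (camera adjusted p = 8.21e-07, adjusted p = 0.53 with an estimated correlation). Il18 was at 1.05 (SE 0.21), Tnfaip3 at 1.68 (SE 0.40), Nfkbia at 0.65 (SE 0.20) and Ccl3 at 2.46 (SE 0.77), and the median was 1.25 without the 3 libraries at odds with their labels. MHC class II genes had a median of 1.07, 13 of 14 positive (camera adjusted p = 0.000127, adjusted p = 0.53 with an estimated correlation). H2-Aa was at 1.33 (SE 0.33), Cd74 at 1.19 (SE 0.32), H2-Ab1 at 1.16 (SE 0.33) and H2-DMa at 1.16 (SE 0.36).

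Fc receptors and antibody handling genes, which bind IgG and pass its signal on, had a median of 0.80, 15 of 18 positive (camera adjusted p = 0.000115, adjusted p = 0.53 with an estimated correlation). Fcgr3 was at 1.53 (SE 0.43), Fcgr4 at 1.57 (SE 0.48) and the adaptor Tyrobp at 1.29 (SE 0.44). Adjusted over the list alone no gene was higher and 1 was lower: Fcgrt, the neonatal Fc receptor that recycles IgG, at -0.61 (SE 0.15). The inhibitory receptor Fcgr2b was at 0.33 (SE 0.21). In the cell cycle list (camera adjusted p = 7.9e-08, adjusted p = 0.601 with an estimated correlation), 18 of 30 genes were higher when adjusted over the list alone, among them Rrm2 at 2.12 (SE 0.49), Birc5 at 3.50 (SE 1.02), Cdkn1a at 1.63 (SE 0.48) and Cdc20 at 3.17 (SE 0.96). This list stood 3.15, -0.06 and 1.69 above the normal diet mean in HFD + PBS replicates 3, 4 and 6. Cholangiocyte markers had a median of 1.04 over 12 (camera adjusted p = 0.00289, adjusted p = 0.53 with an estimated correlation). Tspan8 was at 2.21 (SE 0.43), Krt7 at 1.16 (SE 0.39) and Prom1 at 3.07 (SE 0.99). Without HFD + PBS replicate 3 the medians were 1.32 for cell cycle, 0.49 for Fc receptors and 0.56 for cholangiocyte markers.

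Mitochondrially encoded genes had a median of -0.78, 12 of 13 negative (camera adjusted p = 4.53e-05, adjusted p = 0.53 with an estimated correlation). mt-Nd3 was at -1.28 (SE 0.25), mt-Nd4l at -1.50 (SE 0.47), mt-Nd6 at -0.76 (SE 0.27) and mt-Atp8 at -1.48 (SE 0.53), and mt-Nd4l and mt-Atp8 overlap their neighbours, so their reads are not fully their own. Male-biased liver genes, which depend on male growth hormone rhythm, had a median of -3.97, 21 of 21 negative (camera adjusted p = 0.00296, adjusted p = 0.821 with an estimated correlation), and the call was lost without normal diet replicate 6 (adjusted p = 0.0811, median -2.06). Mup1 and Hsd3b5 had 0 counts in all HFD + PBS libraries, and the median was -3.97 with them at the bound that 3 counts over the group give. Mup3 had 93.7 ± 58.5 CPM against 5003 ± 4433 (-5.74, SE 1.26), and Mup21, Elovl3 and Mup11 were at -5.09 (SE 1.60), -9.16 (SE 3.00) and -9.74 (SE 3.25). Many Mup genes are near-identical, and the reads of such members may not be told from one another. How far this holds for Mup3 and Mup21 was not tested. Against the normal diet mean this list stood at -1.72, -3.29 and -3.98 in HFD + PBS replicates 3, 4 and 6, and at 0.53, -2.44 and 1.97 in normal diet replicates 4, 5 and 6, where HFD + PBS replicate 6 and normal diet replicate 5 are the libraries without Y-linked reads.

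The other called lists each lost the call with some library left out. Interferon response genes had a median of -0.35 (camera adjusted p = 0.00854, adjusted p = 0.849 with an estimated correlation). Irf9 was at -0.63 (SE 0.19) and Rsad2 at -1.57 (SE 0.56), and the adjusted p was 0.318 without normal diet replicate 5 and 0.848 without HFD + PBS replicate 4. Acute phase genes had a median of 0.55 (camera adjusted p = 0.0155, adjusted p = 0.849 with an estimated correlation). Steap4 was at 1.66 (SE 0.68), Mt2 at 3.14 (SE 1.28) and Saa1, a major serum amyloid, at 0.07 (SE 1.60), and the adjusted p was 0.348 without normal diet replicate 6 and 0.659 without HFD + PBS replicate 4. Female-biased genes had a median of 0.53 (camera adjusted p = 0.00854, adjusted p = 0.821 with an estimated correlation). The estrogen sulfotransferase Sult1e1 was at 7.89 (SE 2.29). Their adjusted p was 0.0845 without normal diet replicate 4, 0.282 without normal diet replicate 6 and 0.0815 without HFD + PBS replicate 6. Extracellular matrix genes had a median of 0.35 (camera adjusted p = 0.0251, adjusted p = 0.849 with an estimated correlation). The growth factor Ccn2 was at 1.75 (SE 0.36), and the adjusted p was 0.615 without normal diet replicate 6. Without HFD + PBS replicate 3 the median of that list was -0.10 and camera's direction turned (adjusted p = 0.768). Kupffer cell markers had a median of 0.55 (camera adjusted p = 0.0162, adjusted p = 0.821 with an estimated correlation). C1qb was at 1.07 (SE 0.36), and the adjusted p was 0.0533 without normal diet replicate 4. T and NK cell markers had a median of 0.78 (camera adjusted p = 0.0191, adjusted p = 0.821 with an estimated correlation). Il2rb was at 0.84 (SE 0.25). Their adjusted p was 0.202 without normal diet replicate 4, 0.056 without normal diet replicate 6 and 0.68 without HFD + PBS replicate 3. With each library left out, the interferon median ran from -0.58 (without HFD + PBS replicate 3) to 0.06 (without HFD + PBS replicate 4), and the acute phase median from -0.01 (without HFD + PBS replicate 4) to 0.97 (without normal diet replicate 5). The female-biased median ran from -0.03 (without normal diet replicate 6) to 4.82 (without normal diet replicate 5). The matrix median ran from -0.10 to 0.605 (without HFD + PBS replicates 3 and 6), and the T and NK cell median from -0.18 (without HFD + PBS replicate 3) to 1.26 (without normal diet replicate 5). Without the 3 libraries at odds with their labels the medians were 3.52 for female-biased, 1.08 for acute phase, 0.855 for matrix and 1.47 for T and NK cell genes, and the interferon call was lost (adjusted p = 0.175). The hepatocyte markers, at a median of -0.20 (camera adjusted p = 0.323), and 14 other lists were not called.

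**Figure D2:**
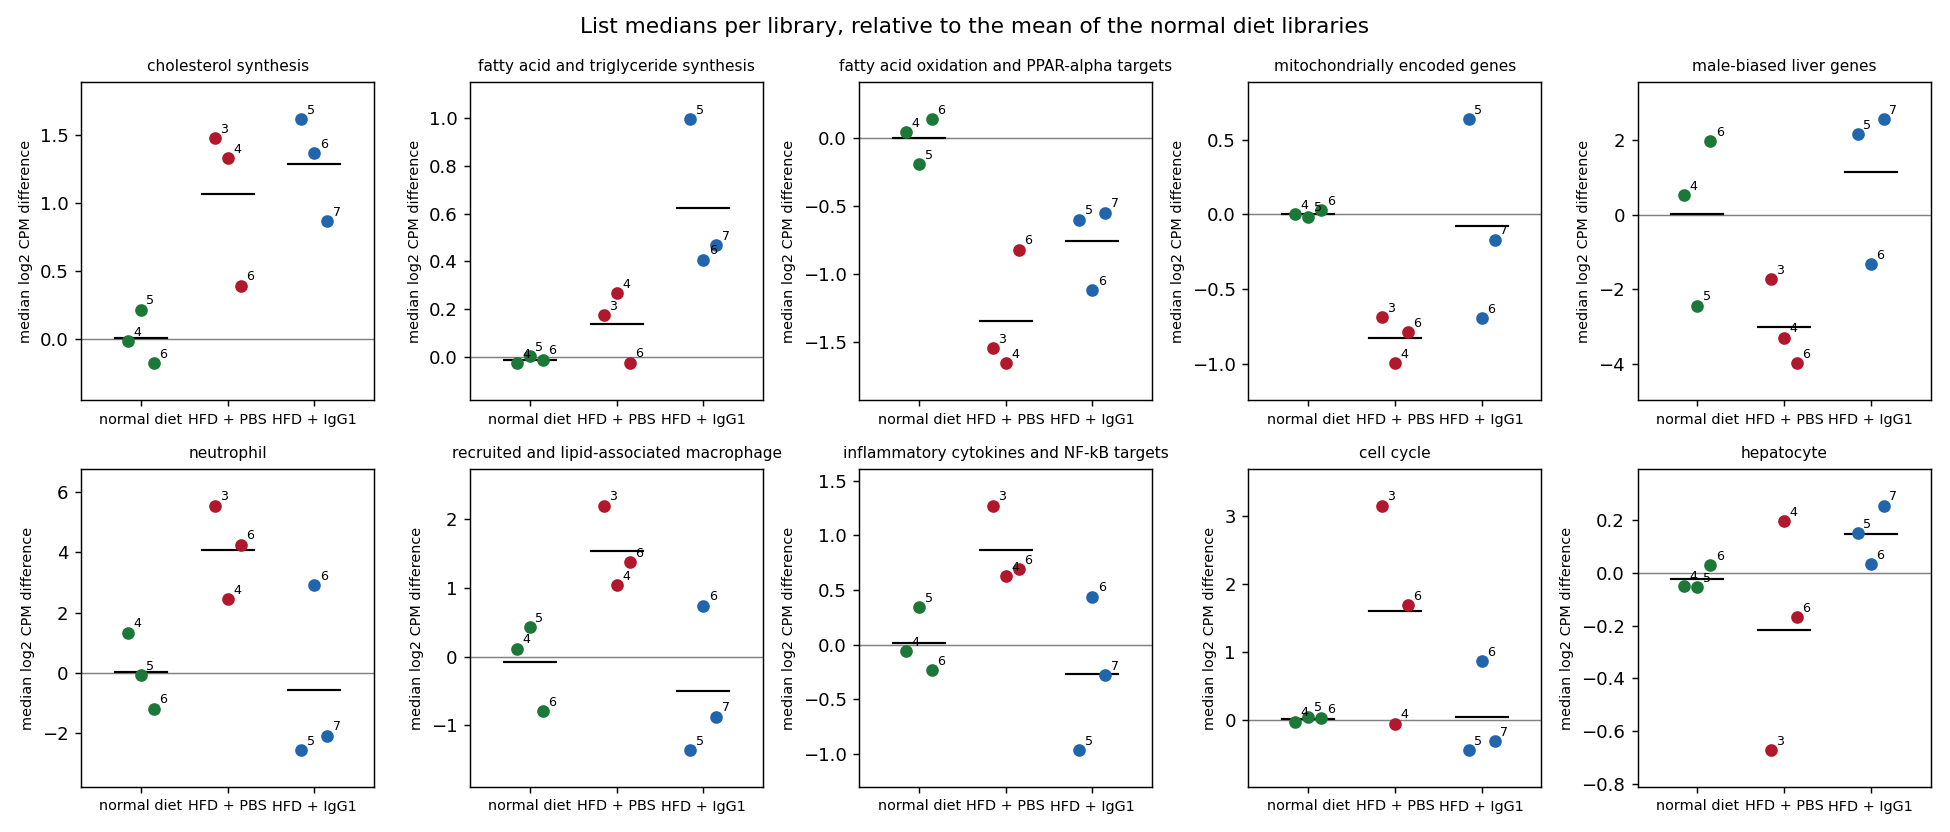
Median log2 CPM difference of each of 10 gene lists in each library, relative to the mean of the normal diet libraries, with points numbered by replicate and bars at group means. HFD + IgG1 replicate 6 stands at 2.91 for neutrophil markers, beside 2.44 to 5.54 in HFD + PBS, while HFD + IgG1 replicates 5 and 7 stand at -2.56 and -2.08.

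The second comparison, HFD + IgG1 against HFD + PBS, asked what differed after the antibody in mice that had been fed the high-fat diet. Several immune gene lists were lower after the antibody: neutrophil markers by a median log2 fold change of -3.00 (14 of 14 negative), recruited and lipid-associated macrophage markers by -1.74 (15 of 15), Fc receptors and antibody handling genes by -1.26 (16 of 18) and MHC class II genes by -1.20 (14 of 14). Cell cycle genes were lower too, by -2.01 (30 of 30), but 3 of them had no overlap between the groups, where chance gives 10%. Against the normal diet mean, HFD + IgG1 replicate 6 stood at 0.743, 0.337 and 0.299 for recruited macrophage, Fc receptor and MHC class II genes. The lowest HFD + PBS libraries stood at 1.04, 0.363 and 0.498, while HFD + IgG1 replicates 5 and 7 were negative for each. For neutrophil markers replicate 6 stood at 2.91, within the HFD + PBS range. The lower values of these immune lists therefore rest largely on replicates 5 and 7. The interferon response list, at -0.285 (camera adjusted p = 0.466), and the complement list, at 0.07 (camera adjusted p = 0.92), were not called. Other lists were higher: male-biased liver genes by 4.77 (21 of 21 positive), fatty acid and triglyceride synthesis by 0.57 (21 of 26), bile acid genes by 0.56 (20 of 24) and fatty acid oxidation by 0.46 (26 of 32). Camera called 24 of the 35 lists, 9 higher and 15 lower, and 0 with an estimated correlation. Adjusted over each list alone, 0 genes passed in 10 of the 24: neutrophil, cell cycle, T and NK cell, B cell, stellate cell, female-biased, acute phase, respiratory chain, hepatocyte and cholesterol synthesis.

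Single genes did not pass: edgeR called 0 of 14763 genes, with a lowest adjusted p of 0.140, while 3569 had an unadjusted p under 0.05 (1863 higher and 1706 lower) where chance gives 738. On the same counts DESeq2 called 1270 genes (549 higher, 721 lower) and limma-voom called 0. The edgeR count was 2356 (1083 higher, 1273 lower) without HFD + IgG1 replicate 6 and 57 with no filter on low counts. It was 556 with only HFD + IgG1 replicate 5, the antibody library whose own label reads IgG1 and the one with a high Apoe count, a lone library assumed to vary like the other groups. With upper-quartile factors the genes with an unadjusted p under 0.05 were 1369 higher and 1996 lower, so the balance of directions depends on the scaling.

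Bdh2, a short-chain dehydrogenase, had 12.6 ± 5.38 CPM after the antibody and 2.50 ± 0.194 in HFD + PBS (mean ± SD, n = 3 each), a log2 fold change of 2.33 (SE 0.38, edgeR adjusted p = 0.140; ENSMUSG00000028167, chromosome 3, 135281221 to 135304426, mm10). Acsm5, a medium-chain acyl-CoA synthetase, was at 1.12 (SE 0.19) and the transporter Abca8a at 2.30 (SE 0.38). Cyp1b1 (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061), a target of the aryl hydrocarbon receptor, had 1.84 ± 0.53 CPM against 8.98 ± 3.10 (-2.28, SE 0.41). The immunoglobulin gene Igkv6-23 was at -2.64 (SE 0.49) and the cold-induced RNA-binding protein Rbm3 at -0.94 (SE 0.18), each of these 6 with an edgeR adjusted p of 0.140.

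Neutrophil markers had 5 of 14 genes without overlap, all lower, where chance gives 10%, and 0 passed when adjusted over the list alone (camera adjusted p = 5.06e-08, adjusted p = 0.515 with an estimated correlation). Stfa2l1 was at -2.73 (SE 0.86), Csf3r at -1.76 (SE 0.59), Cxcr2 at -2.56 (SE 0.91) and Retnlg at -2.72 (SE 1.19). Recruited macrophage markers, of which 8 of 15 were lower when adjusted over the list alone (camera adjusted p = 5.06e-08, adjusted p = 0.515 with an estimated correlation), included Trem2 at 2.78 ± 2.28 against 14.9 ± 3.96 CPM (-2.41, SE 0.66), Spp1 at -1.56 (SE 0.35), Cd63 at -1.88 (SE 0.58) and Lgals3 at -1.75 (SE 0.55). Kupffer cell markers had a median of -0.82, 12 of 13 negative (camera adjusted p = 3.09e-06, adjusted p = 0.521 with an estimated correlation). C1qa, C1qb and C1qc, which Kupffer cells share with other macrophages, were at -1.24 (SE 0.35), -1.30 (SE 0.36) and -1.29 (SE 0.38), and Vsig4 at -1.26 (SE 0.44). Inflammatory cytokines and NF-kB targets had a median of -0.99, 25 of 26 negative (camera adjusted p = 1.67e-08, adjusted p = 0.515 with an estimated correlation). Nfkbia was at -0.86 (SE 0.20), Ccl3 at -2.81 (SE 0.79), Vcam1 at -1.85 (SE 0.51) and Tnfaip3 at -1.30 (SE 0.39). Without HFD + IgG1 replicate 6 the medians were -7.34 for neutrophil, -1.56 for Kupffer cell and -1.54 for inflammatory genes. Against the normal diet mean, that replicate stood at 0.396 for Kupffer cell and 0.439 for inflammatory genes. The lowest HFD + PBS libraries stood at 0.589 and 0.623.

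In the Fc receptor list, 13 of 18 genes were lower when adjusted over the list alone (camera adjusted p = 9.65e-08, adjusted p = 0.515 with an estimated correlation), and the median was -2.06 without HFD + IgG1 replicate 6. The activating receptors Fcgr3 and Fcgr1 were at -1.65 (SE 0.43) and -1.21 (SE 0.34), and the signalling genes Vav1 and Ptpn6 at -1.66 (SE 0.39) and -0.94 (SE 0.26). The inhibitory receptor Fcgr2b was at 81.8 ± 18.3 against 108 ± 20.8 CPM (-0.40, SE 0.21). In the MHC class II list, 10 of 14 were lower when adjusted over the list alone (camera adjusted p = 6.99e-07, adjusted p = 0.515 with an estimated correlation). H2-DMa was at -1.41 (SE 0.36), Cd74 at -1.20 (SE 0.32), H2-Ab1 at -1.25 (SE 0.33) and H2-Aa at -1.21 (SE 0.33). B cell and plasma cell markers had a median of -0.88, 12 of 16 negative (camera adjusted p = 0.00114, adjusted p = 0.515 with an estimated correlation). Igha was at -1.07 (SE 0.28) and Ighm at -2.47 (SE 0.86). T and NK cell markers had a median of -1.44 (camera adjusted p = 0.000246, adjusted p = 0.521 with an estimated correlation), or -0.66 without HFD + PBS replicate 3, with Cd28 at -2.15 (SE 0.65), Cd3e at -1.68 (SE 0.52), Cd8a at -2.91 (SE 0.96) and Gzmb at -1.86 (SE 0.64).

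Of the 30 cell cycle genes (camera adjusted p = 7.28e-07, adjusted p = 0.521 with an estimated correlation), none passed when adjusted over the list alone (lowest adjusted p = 0.056). Against the normal diet mean the list stood at 3.15, -0.06 and 1.69 in HFD + PBS replicates 3, 4 and 6. It stood at -0.45, 0.86 and -0.31 in HFD + IgG1 replicates 5, 6 and 7. Rrm2 was at -1.89 (SE 0.48), Ccnb2 at -2.78 (SE 0.85), Mcm7 at -0.63 (SE 0.20) and Mcm3 at -1.44 (SE 0.47). Extracellular matrix genes had a median of -0.86, 29 of 30 negative (camera adjusted p = 1.59e-06, adjusted p = 0.521 with an estimated correlation). Ccn2 was at 6.96 ± 3.24 against 27.1 ± 6.79 CPM (-1.96, SE 0.37) and the basement membrane collagen Col4a2 at -0.70 (SE 0.20). Without HFD + PBS replicate 3 the medians were -1.07 for cell cycle and -0.42 for matrix genes. Stellate cell and fibroblast markers had a median of -0.36 (camera adjusted p = 0.00094, adjusted p = 0.521 with an estimated correlation). Pdgfra was at -1.16 (SE 0.37) and Dcn at -0.67 (SE 0.24).

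Male-biased liver genes (camera adjusted p = 4.76e-05, adjusted p = 0.521 with an estimated correlation) had 13 of 21 genes without overlap, all higher, where chance gives 10%, and 4 passed when adjusted over the list alone. These were Mup3 (5.93, SE 1.27), Mup21 (5.90, SE 1.66), Cyp2u1 (4.77, SE 1.09) and Serpina12 (2.26, SE 0.61). Female-biased genes had a median of -2.76, 19 of 19 negative (camera adjusted p = 0.000942, adjusted p = 0.521 with an estimated correlation). Sult1e1 was at -5.16 (SE 1.95), Cyp3a41a at -8.40 (SE 3.66), Cyp3a16 at -6.03 (SE 2.63) and Cyp3a41b at -7.96 (SE 3.69), of which the Cyp3a members share reads. HFD + PBS holds 1 library without Y-linked reads and HFD + IgG1 none, and HFD + IgG1 replicate 6, which holds them, stood at -1.32 for the male-biased list against 2.16 and 2.56 in HFD + IgG1 replicates 5 and 7. The female-biased median was -6.43 without HFD + IgG1 replicate 6 and -1.18 without the 3 libraries at odds with their labels.

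Fatty acid and triglyceride synthesis genes (camera adjusted p = 0.000317, adjusted p = 0.521 with an estimated correlation) had 6 of 26 higher when adjusted over the list alone, including Pklr at 1.06 (SE 0.24), Srebf1, the transcription factor of lipogenesis, at 1.47 (SE 0.37), Me1 at 1.56 (SE 0.42) and Gpam at 1.14 (SE 0.33). Their median was 0.34 without the library with a high Apoe count, and without the 3 libraries at odds with their labels the call was lost (adjusted p = 0.0739). Scd1 was at 0.91 (SE 0.44), Fasn at 0.83 (SE 0.40) and Cd36, a fatty acid transporter, at -1.08 (SE 0.40). Bile acid genes (camera adjusted p = 0.000126, adjusted p = 0.515 with an estimated correlation) included Cyp8b1 at 222 ± 161 against 13.4 ± 4.23 CPM (4.05, SE 0.72), Abcc3 at 0.79 (SE 0.17), Akr1c6 at 1.09 (SE 0.30) and the export pump Abcc4 at -1.11 (SE 0.29), while Cyp7a1 was at 1.23 (SE 0.74). Fatty acid oxidation genes (camera adjusted p = 0.000129, adjusted p = 0.521 with an estimated correlation) included Ppara at 1.37 (SE 0.31), Hadh at 0.81 (SE 0.20), Acaa2 at 0.95 (SE 0.27) and Acads at 0.72 (SE 0.22), with Cpt1a at 0.02 (SE 0.23), and the median was 0.71 without those 3 libraries, 0.28 without HFD + PBS replicate 4 and 0.87 without HFD + PBS replicate 6. Xenobiotic metabolism genes had a median of 0.69 (camera adjusted p = 0.00695, adjusted p = 0.515 with an estimated correlation), or 0.46 without HFD + PBS replicate 3, with the carboxylesterase Ces1f at 4.02 (SE 0.89), Cyp2c50 at 0.78 (SE 0.20) and the receptor Nr1i3 at 0.60 (SE 0.17).

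Mitochondrially encoded genes had a median of 0.83, 13 of 13 positive (camera adjusted p = 9.79e-05, adjusted p = 0.521 with an estimated correlation), 0.47 without the library with a high Apoe count and 0.455 without the 3 libraries at odds with their labels. mt-Nd3 was at 1.03 (SE 0.25), mt-Nd4l at 1.66 (SE 0.47), mt-Nd4 at 1.02 (SE 0.33) and mt-Nd2 at 0.81 (SE 0.28). Nuclear-encoded respiratory chain genes had a median of 0.42, 33 of 33 positive (camera adjusted p = 3.05e-05, adjusted p = 0.605 with an estimated correlation). Of these, 1 had no overlap between the groups, where chance gives 10%. Sdha was at 0.74 (SE 0.25), Uqcrc2 at 0.57 (SE 0.22), Ndufa9 at 0.53 (SE 0.22) and Atp5o at 0.61 (SE 0.25), and the median was 0.22 without HFD + IgG1 replicate 7.

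The remaining called lists each lost the call with some library left out. Acute phase genes had a median of -0.94 (camera adjusted p = 5.59e-05, adjusted p = 0.533 with an estimated correlation, and camera adjusted p = 0.0603 without HFD + PBS replicate 4). Of the 27 tested, 2 had no overlap between the groups, where chance gives 10%. Socs3 was at -1.96 (SE 0.83), Lbp at -0.94 (SE 0.45) and Saa1 at -1.71 (SE 1.65). The acute phase median was -0.58 without HFD + PBS replicate 4 and -1.95 without HFD + IgG1 replicate 6. Endothelial markers had a median of -0.27 (camera adjusted p = 0.00695, adjusted p = 0.602 with an estimated correlation). Lyve1 was at -1.63 (SE 0.37), and the adjusted p was 0.103 without HFD + PBS replicate 4 and 0.247 without HFD + IgG1 replicate 7. The endothelial median was -0.42 without HFD + PBS replicate 3 and -0.17 without HFD + IgG1 replicate 7. Cholangiocyte markers had a median of -0.94 (camera adjusted p = 0.0171, adjusted p = 0.521 with an estimated correlation). Tspan8 was at -1.82 (SE 0.42) and Krt7 at -1.42 (SE 0.39). Their adjusted p was 0.14 without HFD + PBS replicate 3 (median -0.60), 0.0616 without HFD + IgG1 replicate 6 and 0.0794 without HFD + IgG1 replicate 7. Hepatocyte markers had a median of 0.29 (camera adjusted p = 0.027, adjusted p = 0.61 with an estimated correlation; 0.443 without HFD + PBS replicate 3). Ttr was at 1.38 (SE 0.41) and Alb at 0.96 (SE 0.37). The hepatocyte median was 0.07 without HFD + PBS replicate 3, 0.52 without HFD + PBS replicate 4 and 0.16 without HFD + IgG1 replicate 7. Cholesterol synthesis genes had a median of 0.19 (camera adjusted p = 0.0171, adjusted p = 0.672 with an estimated correlation). Sqle was at -0.09 (SE 0.38). Camera's direction turned without HFD + PBS replicate 6 (adjusted p = 0.921) and without the 3 libraries at odds with their labels (adjusted p = 0.0775), and the adjusted p was 0.147 without HFD + IgG1 replicate 5 and 0.0985 without HFD + IgG1 replicate 6. With each library left out the median ran from -0.02 to 0.41 (without HFD + PBS replicates 6 and 3). Plin2 at 0.26 (SE 0.40), Cidec at 0.46 (SE 0.38) and Pparg at 0.08 (SE 0.22) belong to the lipid droplet list, 1 of 11 not called.

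**Figure D3:**
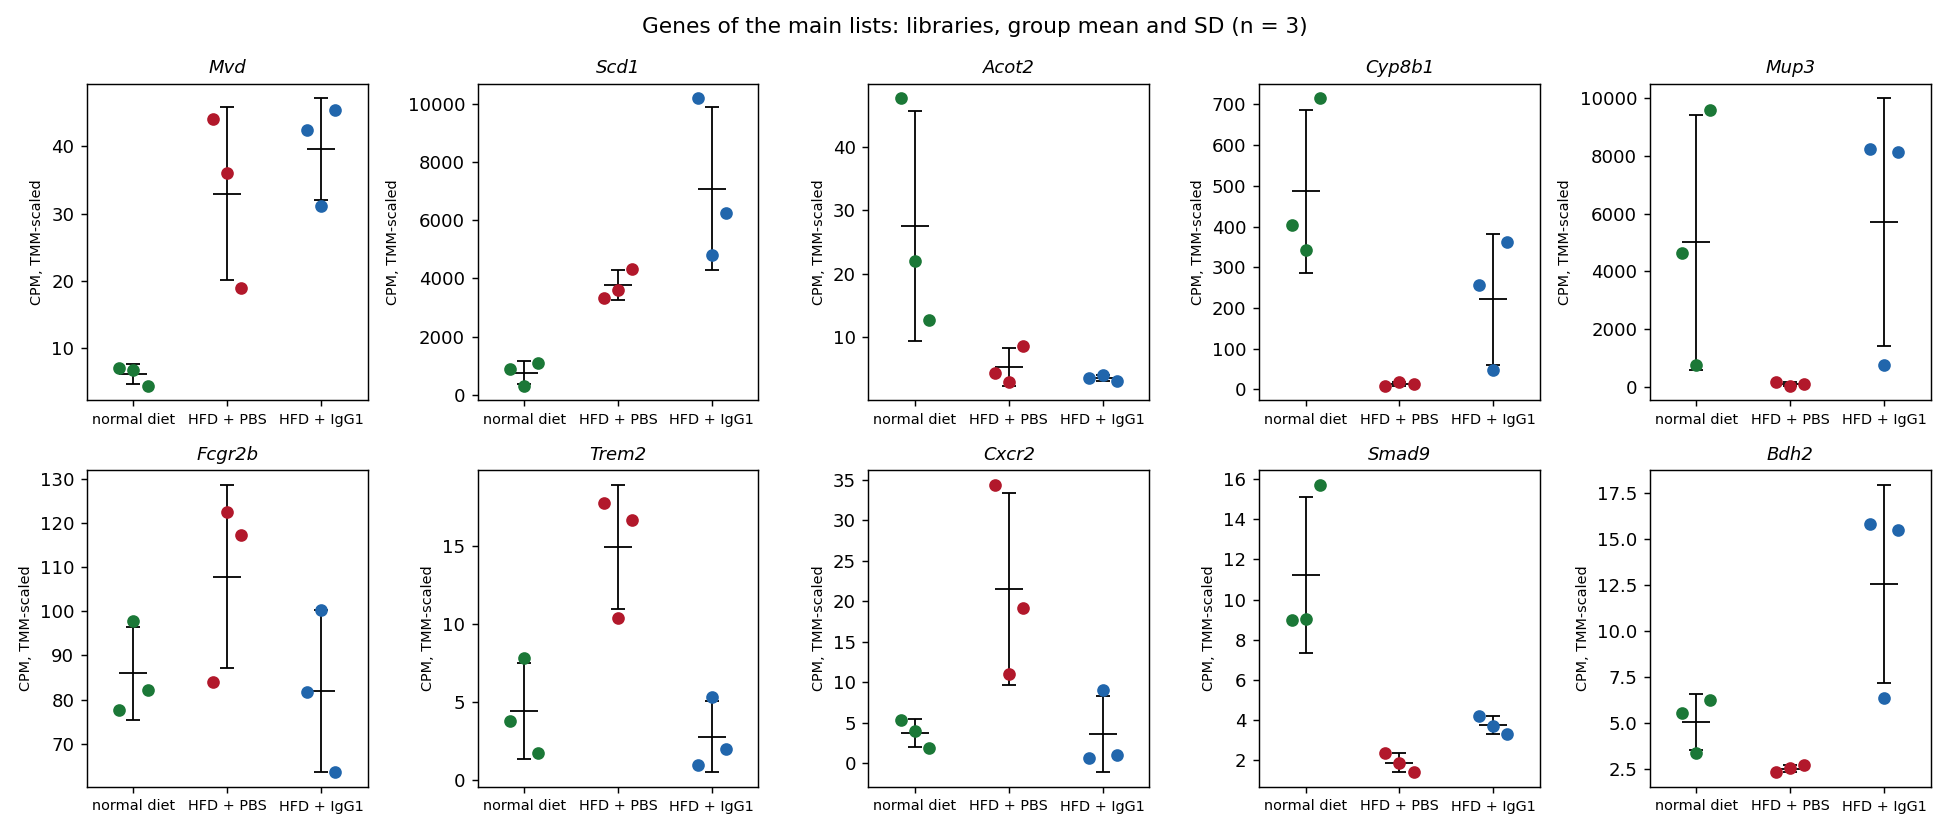
CPM of 10 named genes, 1 point per library, with the group mean and SD (n = 3). Mvd stands at 33.0 and 39.6 CPM in the high-fat diet groups against 6.12 in normal diet, while Cyp8b1 stands at 13.4 in HFD + PBS against 222 after the antibody.

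The third comparison, HFD + IgG1 against normal diet, asked what still differed from the control diet after the antibody. Cholesterol synthesis genes were higher, with a median log2 fold change of 1.31 and 25 of 25 positive, as were fatty acid and triglyceride synthesis genes, with a median of 0.61 (20 of 26). Fatty acid oxidation genes were lower, with a median of -0.80 (30 of 32 negative), as were interferon response genes, with a median of -0.66 (35 of 37). Camera called 19 of the 35 lists, 6 higher and 13 lower, and 0 with an estimated correlation. Adjusted over each list alone, 0 genes passed in 16 of the 19, all but the cholesterol synthesis, fatty acid and triglyceride synthesis and fatty acid oxidation lists. It called 12 without the 3 libraries at odds with their labels.

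Single genes did not pass: edgeR called 0 of 14763 genes, with a lowest adjusted p of 0.158, while 1040 had an unadjusted p under 0.05 (566 higher and 474 lower) where chance gives 738. Other splits of the same 6 libraries gave 130 to 2895 such genes, so 1040 does not stand out from regrouping. On the same counts DESeq2 called 101 genes (57 higher, 44 lower) and limma-voom called 0. The edgeR count was 6 without HFD + IgG1 replicate 6 and 6 with no filter on low counts. It was 3 with only the 6 libraries compared (Mvd, Fdps and Slc22a5) and 3 with only HFD + IgG1 replicate 5, the antibody library whose own label reads IgG1 (Apoe, Ppp1r3b and Cyp2b9). That lone library is assumed to vary like the other groups, and its Apoe call restates its high Apoe count. Slc22a5, Ppp1r3b and Cyp2b9 are named after their values were seen.

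Mvd had 39.6 ± 7.54 CPM after the antibody and 6.12 ± 1.47 in normal diet (mean ± SD, n = 3 each), a log2 fold change of 2.69 (SE 0.33, edgeR adjusted p = 0.158). Fdps was at 3.14 (SE 0.43, edgeR adjusted p = 0.194). Scd1, the desaturase that makes monounsaturated fatty acids (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, mm10), had 7081 ± 2791 against 759 ± 397 CPM (3.22, SE 0.48, edgeR adjusted p = 0.236). Nceh1, a cholesterol ester hydrolase, was at -1.39 (SE 0.23), Txnip, a glucose-responsive inhibitor of thioredoxin, at -1.55 (SE 0.26) and Dnmbp at -1.10 (SE 0.19), with edgeR adjusted p of 0.253, 0.253 and 0.322.

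In the cholesterol synthesis list, 23 of 25 genes were higher when adjusted over the list alone, and 23 had no overlap between the groups, where chance gives 10% (camera adjusted p = 1.01e-30, adjusted p = 0.363 with an estimated correlation). Pmvk was at 1.22 (SE 0.20), Lss at 1.90 (SE 0.36) and Sqle at 1.77 (SE 0.39). Of the fatty acid and triglyceride synthesis genes, 13 of 26 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.06e-08, adjusted p = 0.363 with an estimated correlation). Fasn, the fatty acid synthase, was at 481 ± 232 against 101 ± 12.9 CPM (2.26, SE 0.41), Srebf1 at 1.92 (SE 0.38) and Thrsp at 2.45 (SE 0.49). Of the fatty acid oxidation genes, 12 of 32 were lower when adjusted over the list alone (camera adjusted p = 5.81e-18, adjusted p = 0.363 with an estimated correlation). Acot2 was at -2.93 (SE 0.54), Cpt1a at -1.03 (SE 0.24), Angptl4 at -1.88 (SE 0.47) and Ehhadh at -2.74 (SE 0.68). Lipid droplet genes had a median of -0.32 (camera adjusted p = 0.00788, adjusted p = 0.525 with an estimated correlation; 0.11 without HFD + IgG1 replicate 6), or -0.52 without HFD + IgG1 replicate 7. Plin2 was at -1.44 (SE 0.40), Plin3 at 0.44 (SE 0.14), Apoa4 at -2.26 (SE 0.81) and Fitm2 at -0.64 (SE 0.25). Cyp7a1 was at 1.996 (SE 0.76), Cidec at -0.69 (SE 0.37), Cd36 at -0.47 (SE 0.40) and Pparg at -0.26 (SE 0.22).

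Interferon response genes (camera adjusted p = 1.89e-06, adjusted p = 0.697 with an estimated correlation) included the GTPases Iigp1 at -0.37 (SE 0.17), Gbp3 at -0.91 (SE 0.41) and Irgm2 at -0.54 (SE 0.25), and Usp18 at -1.20 (SE 0.54). Their median was -0.43 without the 3 libraries at odds with their labels and -0.425 without normal diet replicate 5. B cell and plasma cell markers had a median of -0.63, 15 of 16 negative (camera adjusted p = 2.64e-05, adjusted p = 0.363 with an estimated correlation). Igha was at -1.04 (SE 0.28), Cd22 at -0.63 (SE 0.31), Mzb1 at -0.73 (SE 0.37) and Pax5 at -1.74 (SE 0.91), and without HFD + IgG1 replicate 7 the median was -0.35 (adjusted p = 0.00862). Nuclear-encoded respiratory chain genes had a median of 0.33, 32 of 33 positive (camera adjusted p = 1.63e-07, adjusted p = 0.697 with an estimated correlation), and all 33 overlapped between the groups. Cox5a was at 0.74 (SE 0.28) and Sdhb at 0.55 (SE 0.25), and the adjusted p was 0.163 without the 3 libraries at odds with their labels. With each library left out the median ran from 0.175 (without HFD + IgG1 replicate 7) to 0.55 (without normal diet replicate 6). Xenobiotic metabolism genes had a median of 0.45 (camera adjusted p = 0.0012, adjusted p = 0.465 with an estimated correlation; 0.0855 without those 3 libraries). Cyp2c55 was at 2.22 (SE 0.62) and Fmo5 at 0.72 (SE 0.22), and the median was 0.265 without HFD + IgG1 replicate 5.

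Other called lists lost the call with some library left out. Extracellular matrix genes were at a median of -0.41 (camera adjusted p = 0.00018, adjusted p = 0.725 with an estimated correlation; 0.144 without normal diet replicate 5), Kupffer cell markers at -0.38 (camera adjusted p = 0.00018, adjusted p = 0.697 with an estimated correlation; 0.0961 without HFD + IgG1 replicate 5) and Fc receptor genes at -0.31 (camera adjusted p = 0.0012, adjusted p = 0.697 with an estimated correlation; 0.153 without HFD + IgG1 replicate 5). Fcgr2b was at -0.07 (SE 0.21), Trem2 at -0.66 (SE 0.65) and Saa1 at -1.63 (SE 1.65). Unfolded protein response genes were at 0.30 (camera adjusted p = 0.000398, adjusted p = 0.697 with an estimated correlation; 0.312 without HFD + IgG1 replicate 7). Manf was at 1.08 (SE 0.38) and Edem1 at 0.59 (SE 0.20). Endothelial markers were at -0.25 (camera adjusted p = 0.0016, adjusted p = 0.697 with an estimated correlation; 0.321 without HFD + IgG1 replicate 7), and lipoprotein genes at -0.19 (camera adjusted p = 0.0114, adjusted p = 0.697 with an estimated correlation; 0.0518 without normal diet replicate 6 and 0.0786 without HFD + IgG1 replicate 6). Stellate cell, acute phase, male-biased, T and NK cell and MHC class II lists had camera adjusted p of 0.0125, 0.0305, 0.0323, 0.0409 and 0.0428, each with an adjusted p of 0.725 to 0.814 with an estimated correlation. All 5 lost the call without normal diet replicate 5 (adjusted p of 0.511, 0.668, 0.247, 0.511 and 0.483, with camera's direction turned for the male-biased list), without HFD + IgG1 replicate 5 (0.143, 0.888, 0.508, 0.0961 and 0.584) and without HFD + IgG1 replicate 7 (0.141, 0.116, 0.439, 0.314 and 0.113). The acute phase list lost it without normal diet replicate 4 too (0.0962), and the T and NK cell list without normal diet replicate 6 (0.0518). With each library left out, medians were farthest from 0 without HFD + IgG1 replicate 6 for Fc receptor (-0.92), Kupffer cell (-0.98), MHC class II (-0.74), acute phase (-1.26), endothelial (-0.385), matrix (-0.69), stellate cell (-0.41) and unfolded protein response genes (0.45). They were nearest to 0 without HFD + IgG1 replicate 5 for Fc receptor (-0.07), Kupffer cell (-0.09) and MHC class II genes (0.01). The same held without HFD + IgG1 replicate 7 for endothelial (-0.07) and unfolded protein response genes (0.01), and without normal diet replicate 5 for matrix (-0.23), stellate cell (-0.07) and acute phase genes (-0.02). The T and NK cell median ran from -0.90 to -0.22 (without normal diet replicates 4 and 5), and the male-biased median from -0.21 to 1.88 (without normal diet replicates 5 and 6). Without the 3 libraries at odds with their labels, 7 lists of this paragraph were not called: matrix (adjusted p = 0.434), Kupffer cell (0.51), Fc receptor (0.677), stellate cell (0.996), acute phase (0.264), T and NK cell (0.564) and MHC class II (0.524). Camera's direction turned for acute phase and MHC class II genes and for the male-biased list (0.00479). Neutrophil markers were not called (camera adjusted p = 0.262): their median was 1.17 while camera's direction was down, and the median was -2.91 without HFD + IgG1 replicate 6. Recruited macrophage markers, at -0.38 (camera adjusted p = 0.128), and inflammatory genes, at -0.27 (camera adjusted p = 0.0796), were not called either.

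The reversal of the diet response asked whether genes that differed one way after the high-fat diet differed the other way after the antibody. Across the 14763 genes, which are not independent replicates, the differences in mean log2 CPM of the first and second comparisons had a correlation of -0.82. Both use the HFD + PBS libraries with opposite sign, which alone gave -0.25 on average in 20 simulations with no antibody effect and -0.49 with no effect at all. The simulations drew each gene independently and so lack the variation that genes of a library share. How far that variation would move the simulated values was not tested. The covariance was -0.51 against -0.09 in the simulations with no antibody effect. Of the genes with an unadjusted p under 0.05 in the first comparison, 95.8% had the opposite sign in the second, against 66.4% in those simulations and 88.7% in those with no effect at all. There were 809 genes higher then lower at an unadjusted p under 0.05 in both, against 130 simulated, and 961 lower then higher, against 103. With no HFD + PBS library shared, the 6 splits of those libraries gave correlations of -0.67 to -0.49. Neutrophil and recruited macrophage markers, Cyp8b1, Ppara, Ccn2 and male-biased genes lay among the genes of opposite sign, whereas cholesterol synthesis genes were positive in the first comparison and near 0 in the second. Scd1 was positive in both, at 2.31 and 0.91.

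**Figure D4:**
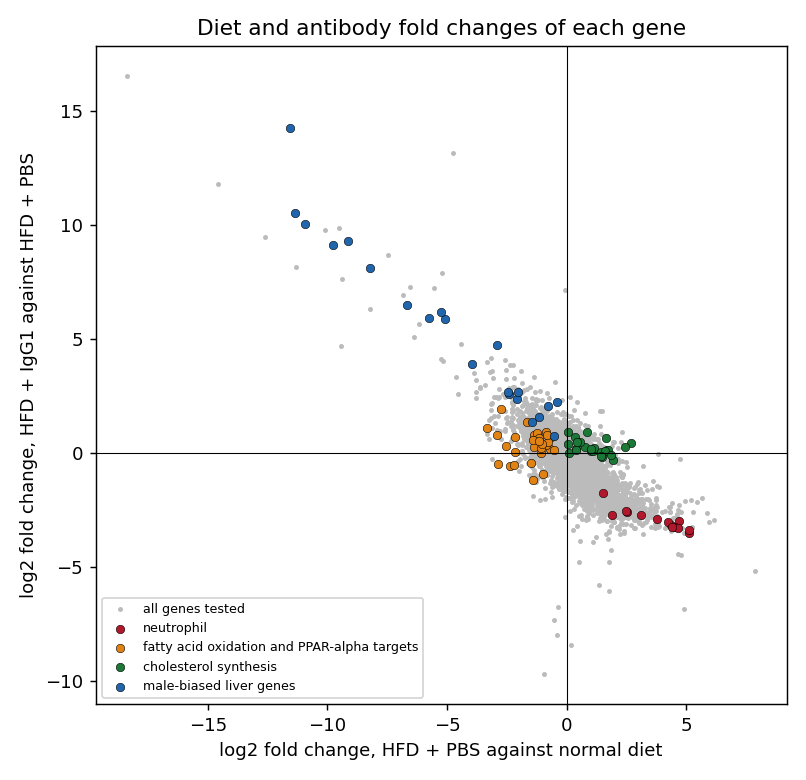
Log2 fold change of each tested gene for HFD + PBS against normal diet (horizontal) and for HFD + IgG1 against HFD + PBS (vertical), with 4 lists coloured. Neutrophil markers lie at high diet and low antibody values (medians 4.30 and -3.00), male-biased genes at low diet and high antibody values (medians -3.97 and 4.77), and cholesterol synthesis genes near 0 on the vertical axis (median 0.19).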

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

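All tests of explanations in this part were chosen after the Apoe counts had been seen. Of 7 measures per library compared over the 9 libraries, 1 had a library far from the others: Apoe, at 16832 CPM in the library labelled HFD + IgG1 replicate 5, with the next at 99.9 CPM and a gap of 0.995 of the whole range. Chance picks out about 1 in 20 such measures.

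The pattern is a liver labelled ApoE−/− with Apoe mRNA at the level of an abundant liver gene. Reads of another liver mixed into this library would add transcripts and remove none, yet 2 of 117 genes within 10 Mb of Apoe lay under 1 in 5 of the lowest of the other 8 libraries, Cyp2a4 (1.07 against at least 118 CPM) and Igsf23 (0.856 against at least 7.79 CPM), and 0 of 8725 elsewhere, which argues against mixing alone. An animal that was not homozygous for the targeted region, or a wrong label, stays open as a candidate explanation: 3 of 202 genes within 10 Mb of Apoe (those 2 and Sae1, at 23.0 against at least 55.5 CPM) lay outside the range of the other libraries, against 28 of 13020 elsewhere, an odds ratio of 6.99 (Fisher's exact test, one-sided p = 0.0115), and 0 of 202 did in each of the other 8. Cyp2a4 is a close paralog of Cyp2a5, so its reads may depend on the sequence of the allele present, and the 3 genes were named because they met this test. No biological explanation was tested, since the design gives no group without the genotype.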

How the results depend on the processing

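The alternatives with Y-linked reads as a covariate and without the 3 libraries at odds with their labels were chosen after seeing the data, and the others before. Genes called, 0 by edgeR in all 3 comparisons (3076, 3569 and 1040 at an unadjusted p under 0.05), stayed at 0 with RLE and upper-quartile factors, at least 1 CPM in 3 libraries, limma-voom, robust = FALSE, a log2 fold change of at least 1, no mitochondrially encoded genes, and Y-linked reads as a covariate. The unadjusted counts of these alternatives were 2700 to 3123, 2698 to 3626 and 766 to 1064. The minimum log2 fold change was applied to the main fit and can only remove calls, so its 0 was fixed in advance. The scaling moved the median of all genes by at most 0.08 on the log2 scale. For HFD + PBS against normal diet, HFD + IgG1 against HFD + PBS and HFD + IgG1 against normal diet in turn, DESeq2 called 1138, 1270 and 101 genes, and a fit with no filter on low counts called 274, 57 and 6. Of the DESeq2 genes tested in both, 1107 of 1107, 1253 of 1253 and 99 of 99 had the same sign in edgeR. With only the 6 libraries compared, the counts were 184, 0 and 3. With only HFD + IgG1 replicate 5, the antibody library whose own label reads IgG1 and the one with a high Apoe count, they were 556 and 3 in the comparisons with that group, where the lone library is assumed to vary like the other groups. Without the 3 libraries at odds with their labels they were 2, 0 and 0. Leaving out each of the 9 libraries gave 0 to 576, 0 to 2356 and 0 to 6 genes, with the highest of each without HFD + IgG1 replicate 6, and 0 to 14 in HFD + PBS against normal diet over the 6 libraries compared. The cause of these differences was not tested.

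The lists called, 20, 24 and 19, were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry (lowest adjusted p of 0.0778, 0.134 and 0.213). Leaving out each library gave 14 to 22, 22 to 24 and 13 to 23 lists. Without the 3 libraries at odds with their labels they were 23, 23 and 12, and with Y-linked reads as a covariate 20, 23 and 16. The replicate numbers do not pair the libraries, since the 5 pairs with the same number had correlations of -0.494 to 0.00692 and the other 22 pairs of -0.347 to 0.425. The replicate block gave 0, 0 and 0 genes (edgeR, with 981, 370 and 396 at an unadjusted p under 0.05) and 15, 19 and 14 lists, and turned the direction of the neutrophil list in HFD + IgG1 against normal diet (adjusted p = 0.00118).

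The correlation of the diet and antibody responses, -0.82, ran from -0.84 to -0.72 with each library left out. With no shared HFD + PBS library it was -0.58, -0.55, -0.54, -0.49, -0.60 and -0.67, where the construction, which removes the shared libraries, takes it toward 0. The comparison limited to genes called could not be run, with 0 called by edgeR. Apoe in its highest library was 377 times the median of the others, and 307 times with plain library totals.

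Camera's direction turned for a few lists, and the cause was not tested. In HFD + PBS against normal diet, extracellular matrix genes turned without HFD + PBS replicate 3 (adjusted p = 0.768, against 0.000104 without replicate 6). In HFD + IgG1 against HFD + PBS, cholesterol synthesis turned without HFD + PBS replicate 6 (0.921, against 5.34e-05 without HFD + IgG1 replicate 7) and without the 3 libraries at odds with their labels (0.0775). In HFD + IgG1 against normal diet, male-biased genes turned without normal diet replicate 5 (0.247), with Y-linked reads as a covariate (0.587) and without those 3 libraries (0.00479). With each library left out their adjusted p ran from 1.1e-06 to 0.508. Without those 3, acute phase (0.264), MHC class II (0.524) and female-biased genes (0.00847) turned there too. In all, by camera's direction for lists and the sign of the fold change for genes, 10 results called in either setting turned, 118 called in neither turned, 206 lost and 407 gained a call, and 6936 kept direction and side of the threshold. At the depth of these libraries, simulated genes changed 2-fold were recovered in 14 to 24% and those changed 4-fold in 69 to 74%. Each gene was drawn independently in that simulation, without the variation that genes of a library share. These percentages therefore do not give the sensitivity in the real data.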

Other observations

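All tests of explanations in this part were chosen after the patterns had been seen, as were the lists described first. Glucose metabolism and insulin signalling genes were not called as a list for the high-fat diet (camera adjusted p = 0.083), but adjusted over the list alone 5 of 25 were lower and 1 higher in HFD + PBS than in normal diet, with 0 past edgeR's test over all genes. Igfbp2, an IGF-binding protein, was at a log2 fold change of -1.14 (SE 0.21), the liver glycogen synthase Gys2 at -1.10 (SE 0.25), the insulin receptor substrate Irs1 at -1.11 (SE 0.27) and the glycolytic regulator Pfkfb3 at 1.41 (SE 0.37). After the antibody Igfbp2, Irs1 and Pfkfb3 were at 0.89 (SE 0.21), 0.97 (SE 0.27) and -1.27 (SE 0.37) against HFD + PBS (list not called, camera adjusted p = 0.131). Against normal diet the gluconeogenic genes G6pc and Pck1 were at -1.89 (SE 0.54) and -1.65 (SE 0.72) after the antibody (list not called, camera adjusted p = 0.628). In the fatty acid and triglyceride synthesis list, not called for the high-fat diet (camera adjusted p = 0.464), 4 of 26 were higher and 2 lower over the list alone, with Scd1 at 2.31 (SE 0.46), Aacs at 1.90 (SE 0.50), Fasn at 1.43 (SE 0.40) and Me1, which makes NADPH, at -2.26 (SE 0.43).

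NRF2 targets and oxidative stress genes went both ways after the high-fat diet, 4 of 27 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.993). The NADPH-making Pgd was at 1.202 (SE 0.33) and Gstm3 at 3.78 (SE 0.69), while catalase, Cat, was at -1.29 (SE 0.34) and Osgin1 at -1.82 (SE 0.44). Complement genes went both ways after the antibody, 6 of 29 higher and 4 lower over the list alone (camera adjusted p = 0.92): C1qa and C1qb were at -1.24 (SE 0.35) and -1.30 (SE 0.36), and C8a and C8g at 1.12 (SE 0.22) and 0.78 (SE 0.23). Of the circadian clock genes 3 of 22 were higher and 1 lower over the list alone after the antibody (camera adjusted p = 0.527), with Hlf at 0.95 (SE 0.24), Clock at 0.80 (SE 0.22) and Ciart at -2.32 (SE 0.71). The time of day of death is not given in the sources used here.

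Fatty acid oxidation genes were lower in HFD + PBS than in normal diet by a median log2 fold change of -1.25. A lower share of hepatocytes would lower hepatocyte markers as much, yet the lowest of the 13 markers was at -0.694. Normal diet replicate 5 and HFD + PBS replicate 6 both lacked Y-linked reads, so sex was balanced between these groups. The median without the 3 libraries at odds with their labels, -1.59, therefore cannot test sex. A longer fast in the normal diet animals stays open and cannot be told apart from the diet. The 5 genes taken as induced by fasting had a median of -0.225 but went both ways. G6pc was at -1.97, Pck1 at -0.351 and Ppargc1a at -0.225, while Tat was at 1.21 and Igfbp1 at 1.86. No biological explanation was tested, and Ppara itself was at -1.65.

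Several immune gene lists were lower in HFD + IgG1 than in HFD + PBS, with neutrophil markers at a median of -3.00. Less blood left in the livers would lower erythroid markers as well, yet the lowest of these was at -0.484 while the highest neutrophil marker was at -1.76. Without the library with a high Apoe count the neutrophil median was -2.55. That median rests on HFD + IgG1 replicate 7, which stood at -2.08 against the normal diet mean, since HFD + IgG1 replicate 6 stood at 2.91. It therefore does not settle how far the library with a high Apoe count, at -2.56, carries the difference. Recruited macrophage, Kupffer cell, Fc receptor, MHC class II and inflammatory lists kept camera's call with each of the 6 libraries left out, that library among them. None of them was called with an estimated correlation. HFD + IgG1 replicate 6 stood near the HFD + PBS libraries for these lists too, so the same limit holds for them. A change in the share of hepatocytes alone would move the markers of other cell types alike. The widest gap between medians, 2.83, lay between neutrophil (-3.00) and erythroid markers (-0.172), so it covers neutrophil markers only. Endothelial and cholangiocyte medians were -0.265 and -0.94, and the other immune lists were not compared in this way. No biological explanation was tested, nor was the choice of livers by staining and TG values, and HFD + IgG1 replicate 6 stood within the range of the HFD + PBS libraries for neutrophil markers.

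With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For HFD + PBS against normal diet, edgeR called 0 genes in the real split (DESeq2 1138, limma-voom 0) and at most 2 in another, with 3076 at an unadjusted p under 0.05 in the real split and at most 1082 in another. With 0 genes in the real split, the number of splits that call as many says nothing. Camera called 20 lists in the real split and at most 20 in another, with 2 of the 10 splits at that count or more. For HFD + IgG1 against HFD + PBS, edgeR called 0 genes in the real split (DESeq2 1270, limma-voom 0) and at most 0 in another, with 3569 and at most 2184 at an unadjusted p under 0.05. Camera called 24 lists and at most 25 in another, with 2 of the 10 as large. For HFD + IgG1 against normal diet, edgeR called 0 genes in the real split (DESeq2 101, limma-voom 0) and at most 110 in another, with 1040 and at most 2895 at an unadjusted p under 0.05. Camera called 19 lists and at most 20 in another, with 3 of the 10 as large. The split with 110 genes set normal diet replicates 4 and 5 and HFD + IgG1 replicate 6 against normal diet replicate 6 and HFD + IgG1 replicates 5 and 7, which points to a structure of the samples. The first principal component, with 50.4% of the variance, held the same order: the HFD + PBS libraries stood at 47.4 to 73.9, HFD + IgG1 replicate 6 at 26.7 and normal diet replicate 5 at 12.5, and the other 4 at -72.2 to -21.1.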
